A study of Homo sapiens with 15 samples.

How the data were processed

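RNA was measured in 15 samples of HEK293 FRT cells that had been transfected with siRNA in 2 rounds 24 h apart and harvested 72 h after the first round, per the labels. RNA was extracted with a Qiagen kit, poly(A) RNA was selected, and libraries were made with a standard Illumina protocol. The authors deposited 1 table of raw read counts per Ensembl gene, with 1 column per library and 60675 genes. The submitters' notes name bcl2fastq 2.20, STAR 2.7.3a, the genome build hg38, R 4.0.0 and edgeR 3.30.3 without saying what each did. The read counter, the annotation release and the strand setting are not given in the sources used here. The deposited values were checked to be whole numbers whose totals differ between libraries. All columns were used.

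Gene symbols were taken from a symbol table that holds 60419 of the gene IDs, 42022 of them with a symbol, and positions from GENCODE 29 on hg38, which holds 58444. The groups follow the labels, which name the control of the ARID knockdowns as wild type or parental and that of the NEAT1 knockdown as parental or control. Both were given scrambled siRNA. Labels number the replicates 1 to 3 in each group and do not say that they are separate cultures or that numbers pair libraries across groups.

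Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, libraries were scaled with TMM factors, and a quasi-likelihood negative binomial model with 1 coefficient per group was fitted. The ARID1A and ARID1B comparisons and the comparison between them used 1 fit of the 9 ARID set libraries, the NEAT1 comparison used a fit of the 6 NEAT1 set libraries, and the comparison of the controls and the differences between the NEAT1 and ARID effects used a fit of all 15. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The SE of a log2 fold change was taken as its size over the square root of the F statistic. CPM values are TMM-normalized over the 15 libraries, with SD over the 3 libraries of a group.

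Gene lists were fixed before the data were examined, as were the comparisons, the rule for naming genes and the settings to be varied. The 30 lists hold 960 symbols and cover chromatin remodelling, RNA processing, stress responses, metabolism, the cell cycle, signalling, development, mitochondrial and noncoding transcripts, and markers of other cell types. Each list was tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation, with fry and with a replicate block. p-values of lists were adjusted within each comparison. Lists with fewer than 5 members tested have counts but no test. Camera called 18 lists for ARID1A, 16 for ARID1B and 15 for NEAT1 of 28 tested each, 10 of 28 between the ARID knockdowns and 19 of 29 between the controls, and none of them was called with an estimated correlation. For the estimated correlation and fry, the contrast was coded as the last coefficient, since their values otherwise depended on the sign of rounded zeros.

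Named genes are the 3 targets, the 8 highest and 8 lowest log2 fold changes per comparison with a control (5 and 5 between the ARID knockdowns), up to 4 called members with the smallest p of each list that camera called or that had at least 5 called members, and up to 6 genes each that changed in the same direction in all 3 knockdowns or in opposite directions with a called difference. The highest and lowest genes had an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups' CPM values, which chance gives in 10% of genes for 3 libraries against 3. Genes without a symbol, clone names, pseudogenes, read-through genes and uncharacterised transcripts were skipped. Some genes that the rule selects are not reported here. Exonic overlap with other genes was computed from the annotation.

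Overlaps of calls were compared with the number for independent lists, with a one-sided Fisher's exact test. For comparisons that share a control, 20 draws of unchanged groups were simulated with the observed dispersions. Sequence features of 3' UTRs of at least 50 bases were tested after log2 fold changes had been regressed on UTR length and GC content and their squares and product, for genes with a mean log2 CPM of at least 1, with residuals limited to 3 on either side. Every 7-mer found in at least 50 genes was ranked in 1 random part of the genes and the chosen one was tested in the other part. Alu elements were called from at least 10 matching words of 12 bases, and groups of genes were compared with 100000 permutations. Medians of nuclear respiratory genes were compared with those of 10000 random lists matched on level. These used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9.

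Total counts ran from 12821939 to 31597126 per library. Counts were simulated with the depths and dispersions of the data, with 200 genes changed in each of 3 draws. On these, the test recovered 74.0%, 66.0% and 68.0% of genes changed 1.5-fold for ARID1A, ARID1B and NEAT1. For the differences between the NEAT1 effect and the ARID1A and ARID1B effects it recovered 49.3% and 53.3%. Far more genes were called in the data, so these rates need not hold there. Of the simulated calls, 4.76% to 8.98% were unchanged genes. Counts of replicates differed by more than sampling, with a chi-square per degree of freedom of 2.67 to 17.7.

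The settings chosen in advance were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, a replicate block, other sets of libraries in the fit, and leaving out each library in turn. Chosen after the data were seen were the NEAT1 set control in place of the ARID set control, thinning of all libraries to 1 depth, and leaving out mitochondrially encoded genes. Splicing was not analysed, since the table holds counts per gene.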

Results

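The data were gene-level read counts from RNA sequencing of poly(A)-selected RNA from HEK293 FRT cells, a human embryonic kidney cell line that carries a recombination site for inserting transgenes. The series addresses paraspeckles, nuclear bodies built on the long noncoding RNA NEAT1, and the SWI/SNF chromatin remodelling complex, in which ARID1A and ARID1B are alternative large subunits. Cells received small interfering RNA (siRNA) against ARID1A, ARID1B or NEAT1, or a scrambled siRNA. The 15 libraries form 5 groups of 3. The ARID set holds the ARID1A knockdown, the ARID1B knockdown and a scrambled control labelled as theirs, and the NEAT1 set holds the NEAT1 knockdown and a scrambled control of its own. Total counts ran from 23201261 to 31597126 per library in the ARID set and from 12821939 to 15685283 in the NEAT1 set. Replicates of a group correlated at 0.989 to 0.996 (Pearson, across genes, log2 of counts-per-million values, CPM). Nothing says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Gene counts do not measure splicing, which the series addresses.

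The targeted genes were examined first. ARID1A (ENSG00000117713, hg38 chromosome 1, 26693236 to 26782110, plus strand) stood at 123 ± 15.3 CPM (SD, n = 3) in the ARID set control and at 37.4 ± 5.65 in its own knockdown, which is 30.9% of the control. Its log2 fold change was -1.70 (SE 0.123, adjusted p = 7.63e-09; all adjusted p of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ARID1B (ENSG00000049618, chromosome 6, 156776020 to 157210779, plus strand) fell from 61.7 ± 2.04 to 17.3 ± 1.74 CPM in its own knockdown, 28.6% of the control (log2 fold change -1.81, SE 0.0763, adjusted p = 1.31e-11). NEAT1 (ENSG00000245532, chromosome 11, 65422774 to 65445540, plus strand, long noncoding) fell from 385 ± 39.6 to 188 ± 38.3 CPM in its own knockdown, 48.8% of the control (log2 fold change -1.04, SE 0.12, adjusted p = 1.45e-05).

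The targets also moved outside their own knockdowns. ARID1A fell by 0.55 on the log2 scale after ARID1B knockdown, to 82.6 ± 14.8 CPM (SD, n = 3, adjusted p = 0.000547), whereas the ARID1B value after ARID1A knockdown was -0.04 (adjusted p = 0.67). With the NEAT1 set control as the reference these values were -0.12 for ARID1A (adjusted p = 0.467) and 0.32 for ARID1B (adjusted p = 0.0066). NEAT1 rose after ARID1B knockdown, from 108 ± 16.9 to 191 ± 25.7 CPM (log2 fold change 0.86, adjusted p = 2.49e-05), and had a log2 fold change of 0.29 after ARID1A knockdown (adjusted p = 0.0791). ARID1B fell after NEAT1 knockdown, from 47.25 ± 5.36 to 30.9 ± 5.13 CPM (log2 fold change -0.62, adjusted p = 0.000525). ARID1A, at 89.8 ± 8.31 and 93.4 ± 13 CPM, had a log2 fold change of 0.06 there (adjusted p = 0.671). NEAT1 was lower in the ARID set control than in the NEAT1 set control (log2 fold change -1.84, adjusted p = 8.58e-10), so its level in both ARID knockdowns lay below that in the NEAT1 set control.

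**Figure D1:**
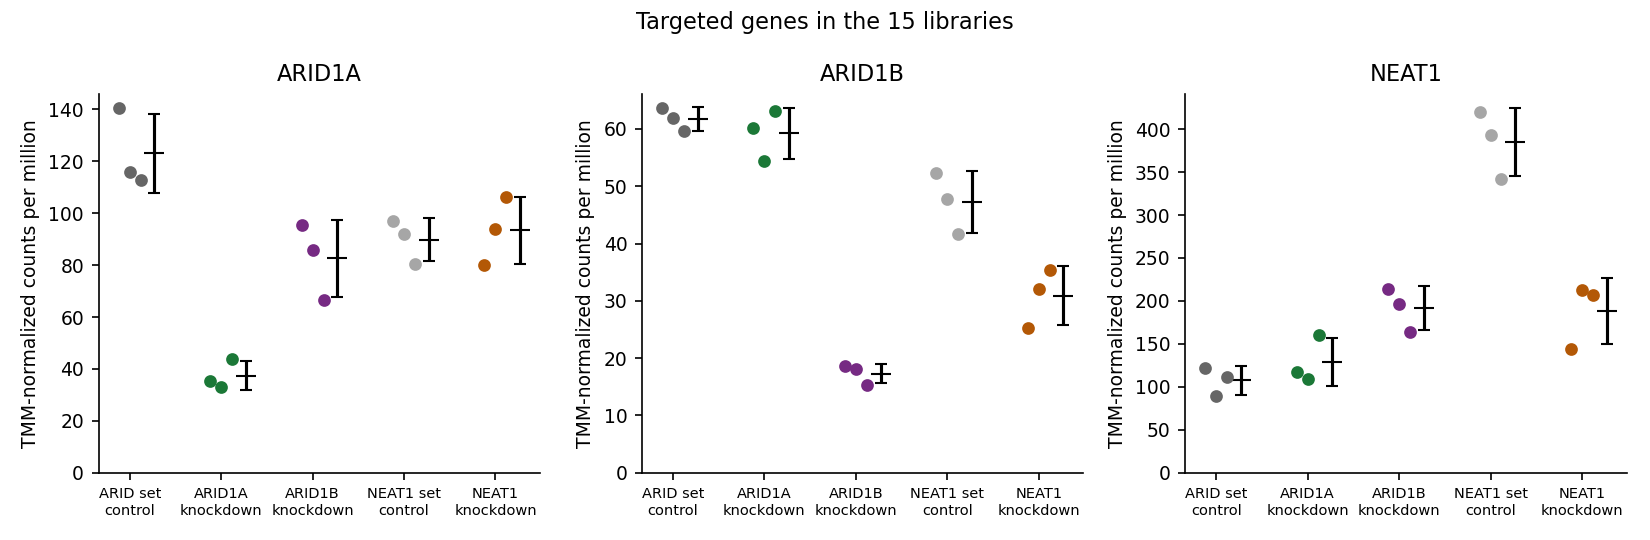
TMM-normalized CPM of ARID1A, ARID1B and NEAT1 in each of the 15 libraries, by group, with the group mean and SD (n = 3). Each gene was lowest in its own knockdown within its own set, and NEAT1 was at 108 ± 16.9 in the ARID set control against 385 ± 39.6 in the NEAT1 set control.

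Both control groups received scrambled siRNA, and they were compared with each other to see how far the sets stand apart. Of 18145 genes tested, 11725 differed between the controls, 5870 higher and 5855 lower in the ARID set control, with 306 at least 2-fold higher and 2372 at least 2-fold lower. Targets of the hypoxia-inducible factors were lower in the ARID set control, 33 of 37, with 2 higher and a median log2 fold change of -0.92 (camera adjusted p = 4.52e-15, adjusted p = 0.21 with an estimated correlation). Replication-dependent histones were also lower, 23 of 29 with none higher (median -1.15, camera adjusted p = 4.11e-06, adjusted p = 0.177 with an estimated correlation). Heat shock genes were higher, 18 of 22 with 1 lower (median 0.48, camera adjusted p = 9.07e-07, adjusted p = 0.21 with an estimated correlation), as were 31 of 40 core spliceosome genes with 3 lower (median 0.38, camera adjusted p = 6.02e-07, adjusted p = 0.218 with an estimated correlation). Upper-quartile scaling left 30.4% of the calls higher, against 50.1% with TMM, and moved the median of all genes from -0.03 to -0.23.

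Over all libraries, the first principal component carried 46.0% of the variance and set the ARID set control apart from the other 4 groups. Its values were 57.2 to 62.2 in that control, 10.8 to 24.5 after ARID1A knockdown, -7.66 to -3.57 after ARID1B knockdown, -32.2 to -20.0 in the NEAT1 set control and -49.7 to -44.7 after NEAT1 knockdown. The root mean square log2 difference between group means was 0.697 between the controls and 0.48 between NEAT1 knockdown and its control. ARID1B knockdown lay nearer to the NEAT1 set control (0.429) than to its own (0.589), and ARID1A knockdown nearer to its own (0.493) than to the NEAT1 set control (0.522). Because the ARID set control stands apart in this way, most groups of genes described for the ARID knockdowns are given with a value against the NEAT1 set control as well, a comparison that was chosen after the data were seen and that crosses the sets.

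**Figure D2:**
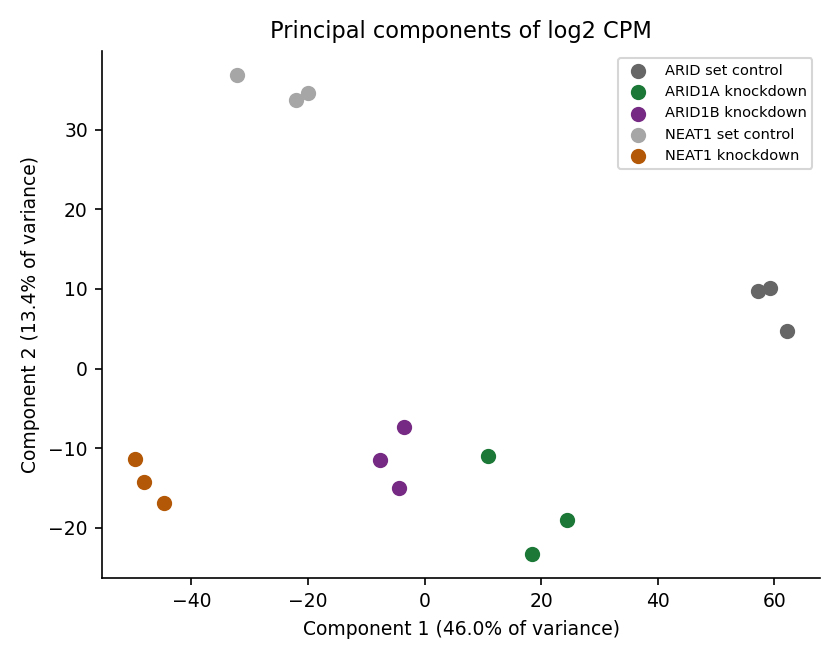
First and second principal components of log2 CPM for the 15 libraries, coloured by group, with the share of variance on each axis (46.0% and 13.4%). The 3 ARID set control libraries sit between 57.2 and 62.2 on the first component, beyond all others.

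Each fixed gene list is given with its calls over all genes tested, and with the count adjusted over the list alone where that differs. The ARID1A knockdown was compared with its scrambled control to find which genes change when this SWI/SNF subunit is reduced. Genes induced by low oxygen, immediate early genes, replication-dependent histones and ribosomal protein genes were higher in the knockdown libraries. Genes for heat shock proteins, spliceosome subunits, heterogeneous nuclear ribonucleoproteins (hnRNPs) and paraspeckle proteins were lower. Camera called these lists with the preset correlation but not with an estimated one, and most of them did not keep their direction against the NEAT1 set control. The highest change was in ANKRD1, a stress-induced ankyrin repeat protein, at 0.597 ± 0.0812 CPM in the control and 14.4 ± 3.75 in the knockdown (SD, n = 3, log2 fold change 4.61, SE 0.215, adjusted p = 6.01e-11). CA9, a carbonic anhydrase of the cell surface and a classical hypoxia target, had a log2 fold change of 4.29 (SE 0.261), and PCK1, the cytosolic enzyme that commits to gluconeogenesis, one of 3.6 (SE 0.274). INHBA, which encodes the activin A subunit, rose by 3.05, the small heat shock protein gene HSPB8 by 2.92, the hypoxia-induced ANKRD37 and HILPDA by 2.76 and 2.7, and the long noncoding RNA GACAT2 by 2.57. Against the NEAT1 set control, ANKRD1 (3.66), INHBA (2.39), GACAT2 (2.10), PCK1 (1.46), HSPB8 (1.33) and CA9 (0.96) were also called higher, while ANKRD37 (-1.74) and HILPDA (-0.88) were called lower.

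The lowest change was in PDPN, the membrane glycoprotein podoplanin, at 53 ± 0.693 CPM in the control and 12.8 ± 1.16 in the knockdown (SD, n = 3, log2 fold change -2.03, SE 0.0711, adjusted p = 3.07e-12). COX6A1, a cytochrome c oxidase subunit, fell by 1.81, ARHGDIA by 1.80, the metallothionein MT2A by 1.78, BABAM2, a subunit of the BRCA1-A complex, by 1.64, SPRYD4 by 1.58 and the adaptor DOK3 by 1.56. All of these but DOK3 were also called lower against the NEAT1 set control, with log2 fold changes of -2.2 for COX6A1, -2.33 for MT2A, -1.64 for BABAM2, -1.29 for SPRYD4 and -1.01 for ARHGDIA; DOK3 was at -0.35 (adjusted p = 0.0864). Among 24 genes called lower by at least 1 on the log2 scale both against the ARID set control and against the ARID1B knockdown, 14 (58.3%) held GCCTCTA or GACCGTT in their 3' untranslated region (UTR), against 9.7% of the 12018 other genes (Fisher's exact test, two-sided, p = 5.52e-09). Among all 1037 genes called lower in both, 279 (26.9%) held either, against 8.2% of the others. Both 7-mers were found on these same data. PDPN held both, COX6A1 and MT2A held GACCGTT, and ARHGDIA, BABAM2, SPRYD4 and DOK3 held GCCTCTA. DOK3 is not one of the genes called lower in both, since it fell by more after ARID1B knockdown. SLC4A4, SAMD9 and FAS, which were higher in ARID1A than in ARID1B knockdown, held GCCTCTA as well. Among genes named below as lower after ARID1A knockdown, MCM5, SMARCC1, PBRM1 and MDM2 held GCCTCTA and PRPF8 held GACCGTT. ARID1B, which was not called after ARID1A knockdown, held GACCGTT too. SPRYD4 shares 3193 exonic bases with GLS2, and MT2A belongs to a family of near-identical copies, so their reads may be split.

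**Figure D3:**
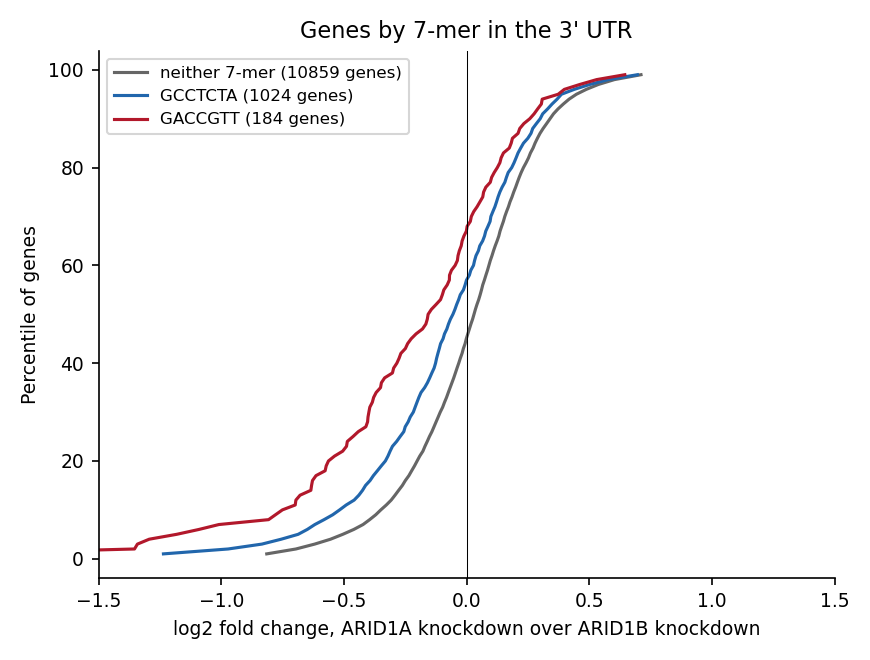
Cumulative distribution of the log2 fold change of ARID1A over ARID1B knockdown (x axis) as the percentile of genes (y axis), for genes whose 3' UTR holds GCCTCTA (1024 genes), GACCGTT (184 genes) or neither. Curves of genes with a 7-mer lie to the left of the curve of genes with neither.

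After ARID1A knockdown, 3 lists of RNA-binding proteins were lower against the ARID set control. Of 37 paraspeckle protein genes tested, 23 were lower and 8 higher (9 higher when adjusted over the list alone), with a median log2 fold change of -0.21 (camera adjusted p = 0.000211, adjusted p = 0.207 with an estimated correlation). SFPQ, an essential paraspeckle protein and splicing factor, fell by 0.93, TAF15 by 0.86, RBM14 by 0.73 and FAM98A by 0.60. Of 40 core spliceosome genes, 24 were lower and 3 higher, 25 and 4 when adjusted over the list alone (median -0.18, camera adjusted p = 6.08e-05, adjusted p = 0.207 with an estimated correlation), among them PRPF8, the central protein of the catalytic core, by 0.74 and SF3A3 of the U2 particle by 0.57. Of 26 hnRNP genes, 17 were lower and 3 higher (median -0.21, camera adjusted p = 0.000121, adjusted p = 0.207 with an estimated correlation). PTBP1, a splicing repressor, fell by 0.62 while its paralogue PTBP2 rose by 0.94, and PTBP2 was also called higher against the NEAT1 set control (0.58). Against that control the medians were 0.07 for paraspeckle proteins, 0.15 for the core spliceosome (19 higher, 3 lower) and 0.09 for hnRNPs. TAF15 (-0.75) and PTBP1 (-0.14) were still called lower, SFPQ (0.34), FAM98A (0.28) and RBM14 (0.16) were called higher, and PRPF8 (-0.09) and SF3A3 (0.09) were not called.

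Of 29 SWI/SNF subunit genes, ARID1A included, 14 were lower and 4 higher after ARID1A knockdown (median -0.15, camera adjusted p = 0.0128, adjusted p = 0.219 with an estimated correlation). SS18 fell by 0.63, PBRM1 by 0.53 and SMARCC1, a core scaffold subunit, by 0.48. Against the NEAT1 set control the median was 0.16, SS18 was still called lower (-0.32), SMARCC1 was called higher (0.29) and PBRM1 was not called (0.16). Of 22 SR protein and SR kinase genes, 12 were lower and 3 higher with TMM scaling but 7 and 8 with upper-quartile scaling (camera adjusted p = 0.0602). SRSF1 fell by 0.81 and SRSF6 by 0.68, and the kinases CLK3 and CLK1, which phosphorylate SR proteins, rose by 0.87 and 0.67. This list had 9 lower and 3 higher against the NEAT1 set control, where SRSF1 (0.00), SRSF6 (0.10) and CLK3 (0.03) were not called and CLK1 was called lower (-0.35).

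Of 37 hypoxia-inducible factor targets, 34 were higher and 1 lower after ARID1A knockdown (median 0.71, camera adjusted p = 1.67e-18, adjusted p = 0.196 with an estimated correlation). SLC2A3, a glucose transporter, rose by 2.43, BHLHE40 by 1.58 and the mitophagy receptor BNIP3 by 1.40. The controls differed by -0.92 in the median of this list, and against the NEAT1 set control 20 of its members were lower and 6 higher after ARID1A knockdown (median -0.27), with BHLHE40 (-0.39) and BNIP3 (-0.27) called lower and SLC2A3 higher (0.32). Immediate early genes were higher against either control. Against the ARID set control 23 of 31 were higher and 4 lower (24 higher over the list alone, median 0.89, camera adjusted p = 2.12e-08, adjusted p = 0.207 with an estimated correlation), and against the NEAT1 set control 21 and 3 (median 0.43, camera adjusted p = 0.000113, adjusted p = 0.498 with an estimated correlation). ATF3 rose by 1.98, the phosphatase DUSP1 by 1.53, JUNB by 1.34 and KLF10 by 1.13, and all of these were also called higher against the NEAT1 set control.

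Stress pathways moved in different directions. Heat shock genes were lower after ARID1A knockdown, 16 of 22 with 3 higher (median -0.32, camera adjusted p = 2.43e-05, adjusted p = 0.207 with an estimated correlation), led by HSPA1A (-1.31), DNAJA1 (-0.90) and HSPA8 (-0.76). Reads of HSPA1A and its near-identical copy HSPA1B may be split between them. Targets of ATF4, the transcription factor of the integrated stress response, were higher, 23 of 35 with 7 lower (median 0.31, camera adjusted p = 0.000685, adjusted p = 0.236 with an estimated correlation). DDIT4, an inhibitor of mTOR signalling, rose by 2.25, DDIT3 by 1.65 and STC2 by 1.18. Of 28 p53 targets, 17 were higher and 4 lower (median 0.22, camera adjusted p = 0.00267, adjusted p = 0.196 with an estimated correlation), with GDF15 at 2.42, the apoptosis gene BBC3 at 1.82 and BTG2 at 1.07, and with MDM2, which targets p53 for degradation, at -0.82. When set against the NEAT1 set control, BBC3 (0.70) and BTG2 (0.83) were called higher, GDF15 (-0.38), MDM2 (-0.43), HSPA1A (-0.68), DDIT4 (-0.35), DDIT3 (-0.27) and STC2 (-0.60) lower, and HSPA8 (0.96), DNAJA1 (0.46) and HSPA1B (0.41) higher. The lists had 12 higher and 1 lower there for heat shock, 8 and 14 for ATF4 targets and 10 and 4 for p53 targets (5 lower over the list alone). The controls differed in the median by 0.48 for heat shock genes, -0.36 for ATF4 targets and -0.04 for p53 targets.

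Ribosomal protein, histone and HOX genes were higher and DNA replication genes lower after ARID1A knockdown against the ARID set control. Of 75 cytosolic ribosomal protein genes, 72 were higher and 1 lower (median 0.38, camera adjusted p = 1.67e-18, adjusted p = 0.273 with an estimated correlation), and 22 were higher and 4 lower against the NEAT1 set control (19 higher over the list alone, median 0.13). RPS18 rose by 0.74 and RPL39 by 0.59, and neither was called against the NEAT1 set control (0.19 and 0.11). Of 26 replication-dependent histones, which share similar copies, 22 were higher and none lower (median 1.22, camera adjusted p = 3.01e-07, adjusted p = 0.196 with an estimated correlation), and the median against the NEAT1 set control was 0.01. DNA replication genes were lower, 25 of 40 with 4 higher (5 over the list alone, median -0.17, camera adjusted p = 0.000664, adjusted p = 0.294 with an estimated correlation), with CCNE1, the cyclin of S phase entry, at -0.73 and the replicative helicase subunit MCM5 at -0.61. Of these genes, 24 were higher and 7 lower against the NEAT1 set control, CCNE1 (-0.24) and MCM5 (-0.18) among the lower. Of 36 HOX genes, 20 were higher and 3 lower (23 higher over the list alone, median 0.25, camera adjusted p = 0.000574, adjusted p = 0.207 with an estimated correlation), led by HOXA13 (1.15) and HOXB5 (0.97), and 21 were higher and 8 lower against the NEAT1 set control (9 lower over the list alone), with HOXB5 called higher (0.35) but HOXA13 at -0.20 (adjusted p = 0.107).

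In all, 9481 of 17365 genes tested were called after ARID1A knockdown, 4887 higher and 4594 lower, with 951 at least 2-fold higher and 163 at least 2-fold lower. The median size of a called change was 0.41 on the log2 scale. Upper-quartile scaling left 66.0% of the calls higher, against 51.5% with TMM, and moved the median of all genes from 0.03 to 0.12. Of 9477 calls also tested against the NEAT1 set control, 2661 (28.1%) were called in the same direction there, 2486 (26.2%) in the opposite direction and 4330 were not called.

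The ARID1B knockdown was compared with the same control to ask which genes change when the other subunit is reduced. Hypoxia targets, histones, ribosomal protein genes, mitochondrial ribosomal RNA and immediate early genes were higher, and heat shock, spliceosome, hnRNP, paraspeckle and DNA replication genes were lower. Camera called these lists with the preset correlation but not with an estimated one. Their medians were smaller or of the other sign against the NEAT1 set control, and the mitochondrial ribosomal RNA MT-RNR1 was lower there (-1.51). PCK1 was at 0.442 ± 0.0856 CPM in the control and 7.15 ± 1.48 in the knockdown (SD, n = 3, log2 fold change 4.02, SE 0.264, adjusted p = 1.73e-09). CA9 rose by 3.84, the histone gene H2BC21 by 3.79, ANKRD37 by 3.77, HILPDA by 3.18, VSTM2B by 3.18, CAPN12 by 3.18 and MIR210HG, host of a microRNA induced by hypoxia, by 3.13. Exons of CAPN12 overlap ACTN4 on the other strand, and among other genes named here ANKRD37 overlaps UFSP2, CA9 ARHGEF39, MBNL1 MBNL1-AS1, BRD7 ADCY7 and ACAT2 SOD2-OT1 in the same way. Strand use in counting is not given, so reads of such genes may be shared. Against the NEAT1 set control, PCK1 (1.88), H2BC21 (1.20), VSTM2B (0.53) and CA9 (0.51) were called higher, ANKRD37 (-0.74), MIR210HG (-0.72) and HILPDA (-0.40) lower, and CAPN12 was at 0.02 (adjusted p = 0.94).

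NCOA5, a nuclear receptor coactivator, had the lowest log2 fold change after ARID1B knockdown, -1.84, at 80.4 ± 3.01 CPM in the control and 22.0 ± 2.64 in the knockdown (SD, n = 3, SE 0.0767, adjusted p = 1.13e-11). CIRBP-AS1 fell by 1.83, ARID1B itself by 1.81, SLC4A4, a sodium bicarbonate cotransporter, by 1.75, DOK3 by 1.68, PRKAR1B, a regulatory subunit of protein kinase A, by 1.63, MBNL1, a splicing regulator, by 1.59 and UTP20, which acts in ribosomal RNA processing, by 1.55. Of these, SLC4A4 (-1.78), ARID1B (-1.45), MBNL1 (-0.70), PRKAR1B (-0.60), DOK3 (-0.48) and CIRBP-AS1 (-0.75) were also called lower against the NEAT1 set control, NCOA5 was at -0.05 (adjusted p = 0.78) and UTP20 at -0.04 (adjusted p = 0.711).

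Paraspeckle protein genes were lower after ARID1B knockdown, 24 of 37 with 5 higher (median -0.33, camera adjusted p = 3.37e-05, adjusted p = 0.25 with an estimated correlation). SFPQ fell from 882 ± 16.4 to 302 ± 28.4 CPM (SD, n = 3, log2 fold change -1.52), RBM12 by 1.01, RBM14 by 0.98 and the SFPQ partner PSPC1 by 0.91. Core spliceosome genes were lower too, 26 of 40 with 5 higher (median -0.32, camera adjusted p = 6.53e-06, adjusted p = 0.25 with an estimated correlation), as were 20 of 26 hnRNP genes with 1 higher (median -0.32, camera adjusted p = 6.53e-06, adjusted p = 0.25 with an estimated correlation). SNRPD3, a protein of the Sm ring, fell by 0.96, HNRNPM by 1.10 and SRSF1 by 1.03. Among SWI/SNF subunits 15 of 29 were lower and 3 higher, ARID1B included (median -0.21, camera adjusted p = 0.00818, adjusted p = 0.25 with an estimated correlation), with PBRM1 at -0.72 and BRD7 at -0.60. The controls differed in the medians by 0.30 for paraspeckle proteins, 0.38 for the core spliceosome, 0.30 for hnRNPs and 0.32 for SWI/SNF subunits. Against the NEAT1 set control the medians were -0.05, 0.08, -0.01 and -0.01. There SFPQ (-0.25), PSPC1 (-0.20), HNRNPM (-0.20), SRSF1 (-0.23) and BRD7 (-0.29) were still called lower, and RBM14 (-0.09), RBM12 (0.12), SNRPD3 (-0.13) and PBRM1 (-0.04) were not called.

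Among the induced groups, 35 of 37 hypoxia targets were higher after ARID1B knockdown and none lower (median 0.93, camera adjusted p = 6.15e-20, adjusted p = 0.25 with an estimated correlation). NDRG1 rose by 2.26, SLC2A3 by 2.51, BHLHE40 by 1.91 and the neuronal enolase ENO2 by 1.42. Of this list, 11 were higher and 5 lower against the NEAT1 set control (median 0.06), with NDRG1 at 0.78 and SLC2A3 at 0.40 called higher and BHLHE40 (-0.07) and ENO2 (-0.10) not called. Of 26 histones 21 were higher and none lower (median 1.51, camera adjusted p = 1.57e-07, adjusted p = 0.25 with an estimated correlation), and 12 of 29 were higher with 1 lower against the NEAT1 set control (median 0.34; 12 and 2 over the list alone). H2BC21, H1-4 (3.52) and H1-2 (2.12) were called higher against either control. Ribosomal protein genes were higher, 73 of 75 with none lower (74 over the list alone, median 0.44, camera adjusted p = 3.99e-19, adjusted p = 0.314 with an estimated correlation). With the NEAT1 set control 37 were higher and 3 lower (45 and 3 over the list alone, median 0.21, camera adjusted p = 2.23e-07, adjusted p = 0.743 with an estimated correlation), with RPL13 at 0.82 and 0.54 against the ARID and NEAT1 set controls.

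Immediate early genes were higher after ARID1B knockdown against either control, 23 of 31 with 3 lower against its own (24 higher over the list alone, median 0.68, camera adjusted p = 1.01e-06, adjusted p = 0.25 with an estimated correlation) and 19 with 2 lower against the NEAT1 set control (20 and 3 over the list alone, median 0.34, camera adjusted p = 1.94e-06, adjusted p = 0.583 with an estimated correlation). DUSP1 rose by 2.02, JUNB by 1.55 and NR4A1 by 1.31. Heat shock genes were lower, 17 of 22 with 2 higher (median -0.46, camera adjusted p = 6.53e-06, adjusted p = 0.25 with an estimated correlation), led by DNAJA1 (-1.40), HSPA8 (-1.34) and HSPH1 (-1.32), and their median against the NEAT1 set control was 0.12, where HSPA8 was called higher (0.38) and DNAJA1 (-0.05) and HSPH1 (0.03) were not called. DNA replication genes were lower, 28 of 40 with 3 higher (29 lower over the list alone, median -0.27, camera adjusted p = 6.53e-06, adjusted p = 0.272 with an estimated correlation), with POLA1 at -0.78; their median against the NEAT1 set control was 0.04, and POLA1 was not called there (adjusted p = 0.967). ATF4 targets were 25 higher and 10 lower of 35 (median 0.36, camera adjusted p = 0.0023, adjusted p = 0.314 with an estimated correlation), and 6 higher and 9 lower of 36 against the NEAT1 set control. Long noncoding RNAs kept in the nucleus or hosting small nucleolar RNAs were 19 higher and 4 lower of 27 (median 0.60, camera adjusted p = 0.000561, adjusted p = 0.259 with an estimated correlation), with MALAT1 at 1.87 and GAS5 at 0.99. Their median against the NEAT1 set control was -0.15, with GAS5 called lower there (-0.23) and MALAT1 not called (-0.33, adjusted p = 0.218).

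ARID1B knockdown gave 11012 calls among 17365 genes, 5661 higher and 5351 lower, with 1413 at least 2-fold higher and 277 at least 2-fold lower; the median size of a called change was 0.48. The count against the NEAT1 set control was 6569. Of 11008 calls tested against both, 2527 (23.0%) went in the same direction there, 1772 (16.1%) in the opposite direction and 6709 were not called. Upper-quartile scaling left 64.8% of the calls higher, against 51.4% with TMM, and moved the median of all genes from 0.03 to 0.15.

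**Figure D4:**
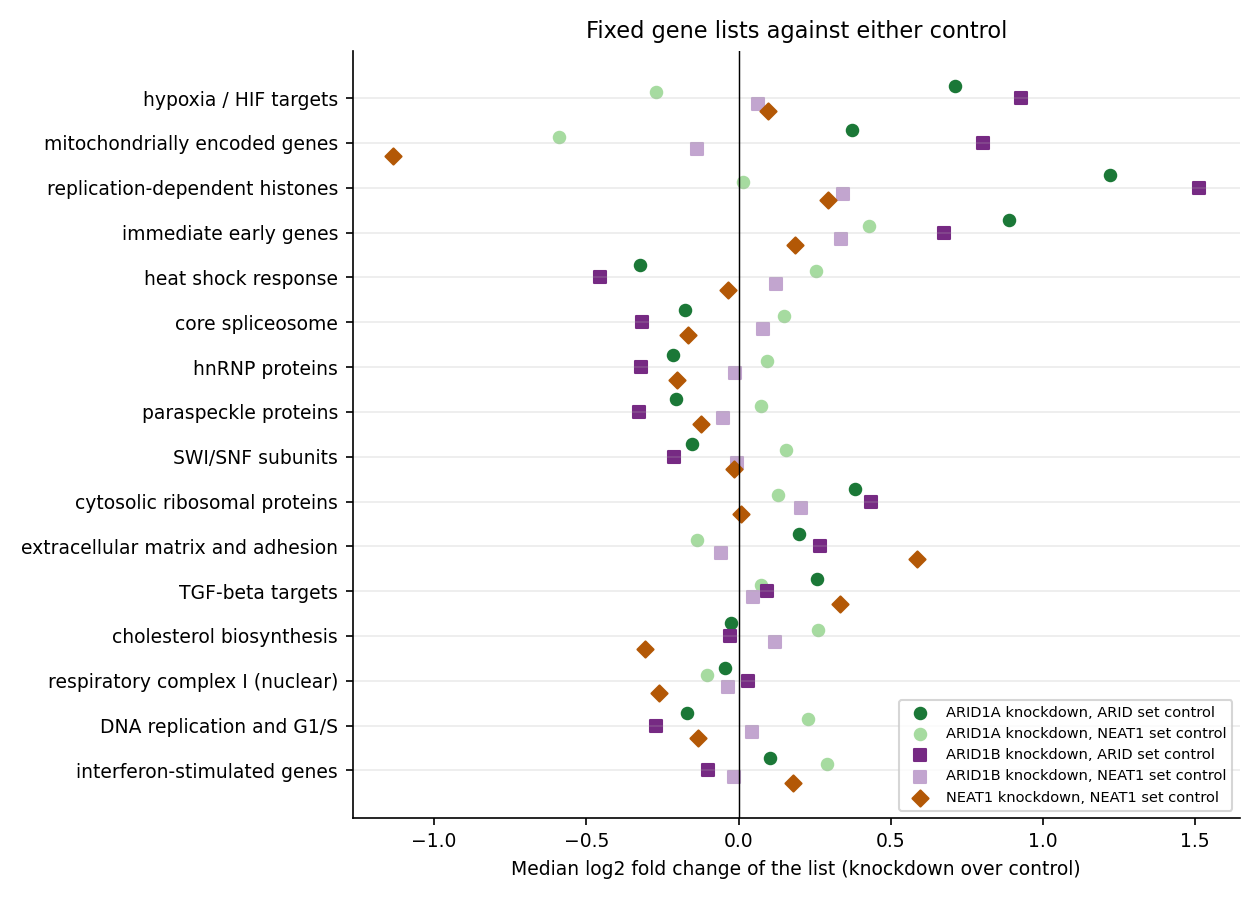
Median log2 fold change (x axis) of 16 fixed gene lists (y axis) for the ARID1A, ARID1B and NEAT1 knockdowns against their own controls and, for the ARID knockdowns, against the NEAT1 set control. Hypoxia targets stand at 0.71 and 0.93 in the ARID knockdowns against their own control and at -0.27 and 0.06 against the other.

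Mitochondrially encoded transcripts took different shares of the counts in the 5 groups. They made up 2.97% ± 0.498 (SD, n = 3) of counts in the ARID set control, 4.71% ± 0.72 after ARID1A knockdown, 7.13% ± 1.58 after ARID1B knockdown, 8.56% ± 0.96 in the NEAT1 set control and 4.24% ± 0.999 after NEAT1 knockdown. After ARID1A knockdown 8 of 15 such genes were higher and none lower (median 0.37, camera adjusted p = 0.0133, adjusted p = 0.556 with an estimated correlation), and after ARID1B knockdown 9 and none (median 0.80, camera adjusted p = 0.00101, adjusted p = 0.488 with an estimated correlation). MT-RNR1 and MT-RNR2, the mitochondrial ribosomal RNAs, rose by 1.62 and 2.15 after ARID1A knockdown and by 2.30 and 3.06 after ARID1B knockdown, and MT-ND4 by 0.81 and 1.72, while MT-ND3 stood at -0.06 and 0.00. The controls differed by -1.15 in the median of this list, and against the NEAT1 set control 9 of the 15 were lower and none higher after ARID1A knockdown (10 lower over the list alone) and 5 and none after ARID1B knockdown, with MT-RNR1 at -2.18 and -1.51. Nuclear copies of the mitochondrial ribosomal RNA genes exist, so reads of these genes may be split.

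The paralogue knockdowns were compared directly to find where they differ. ARID1A knockdown had more ANKRD1 than ARID1B knockdown, at 14.4 ± 3.75 and 3.98 ± 0.419 CPM (SD, n = 3, log2 fold change 1.85, SE 0.156, adjusted p = 1.41e-07), and more SLC4A4 (2.2), GACAT2 (1.79), INHBA (1.74) and the neuronal microtubule protein MAP2 (1.57). It had less MT2A (-2.35), COX6A1 (-2.35), PDPN (-2.06), VSTM2B (-1.89) and the gelatinase MMP2 (-1.73). Targets of p53 were higher in ARID1A than in ARID1B knockdown, 16 of 28 with none lower (20 over the list alone, median 0.19, camera adjusted p = 4.28e-05, adjusted p = 0.0781 with an estimated correlation), led by the phosphatase PPM1D (0.74), the death receptor FAS (0.51) and AEN (0.40). Interferon-stimulated genes were also higher, 15 of 31 with none lower (16 over the list alone, median 0.22, camera adjusted p = 0.00202, adjusted p = 0.0781 with an estimated correlation), with IFI35 at 0.73, SAMD9 at 0.70, OAS3 at 0.56 and IFIH1, a sensor of double-stranded RNA, at 0.47. Hypoxia targets were lower, 24 of 37 with 2 higher (25 lower over the list alone, median -0.22, camera adjusted p = 1.22e-08, adjusted p = 0.708 with an estimated correlation), with NDRG1 at -1.19, ANKRD37 at -1.0, the collagen prolyl hydroxylase subunit P4HA1 at -0.67 and ENO2 at -0.52. DNA replication genes were 23 higher and 7 lower of 40 (24 higher over the list alone, median 0.15, camera adjusted p = 0.00862, adjusted p = 0.744 with an estimated correlation), although CCNE1 (-0.46) and MCM5 (-0.33) were lower.

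This comparison does not use the control libraries in its contrast. It called 7109 of 17365 genes, 3677 higher and 3432 lower in ARID1A knockdown, with 127 at least 2-fold higher and 233 at least 2-fold lower and a median size of 0.33. Replication-dependent histones were 11 lower and 1 higher of 26 (2 higher over the list alone, median -0.30, camera adjusted p = 0.0107, adjusted p = 0.729 with an estimated correlation), with H2BC21 at -1.56. Genes for paraspeckle proteins were 17 higher and 5 lower of 37 (18 higher over the list alone, median 0.09, camera adjusted p = 0.0244, adjusted p = 0.744 with an estimated correlation), with SFPQ at 0.58 and PSPC1 at 0.55.

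The calls of the ARID knockdowns overlapped. They shared 3635 genes called higher, against 1593 for independent lists, and 3565 called lower, against 1416, while 151 were higher in ARID1A and lower in ARID1B knockdown and 194 the reverse. Fold changes correlated at r = 0.794 across 17365 genes, which are not independent replicates. Unchanged groups simulated against the same control libraries gave r = 0.485 and no shared calls in 20 draws. The covariance was 0.26 against 0.0148 in the simulation. The controls are too few to split into 2 parts of at least 2 libraries, so part of the excess may come from the shared control. Of 7198 genes called in one direction in both, 5782 (80.3%) were also called in that direction in the NEAT1 set control against the ARID set control, and 139 in the opposite one. Against either control, 946 genes were called in one direction in both knockdowns, 610 higher and 336 lower; TXNIP, RHOB, ANKRD1, DUSP1, SLC2A3 and BTG2 were among the higher ones and TAF15 and MDM2 among the lower.

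The NEAT1 knockdown was compared with its own control to ask which genes change when the RNA scaffold of paraspeckles is reduced. Genes of the extracellular matrix and of TGF-beta signalling were higher in the knockdown libraries. Mitochondrially encoded genes, nuclear genes of respiratory complex I, cholesterol synthesis genes, hnRNPs and spliceosome genes were lower. Camera called these lists with the preset correlation but not with an estimated one. PTPRZ1, a receptor tyrosine phosphatase, had the highest log2 fold change, 3.31 (SE 0.288, adjusted p = 1.06e-06), at 0.367 ± 0.0913 CPM in the control and 3.70 ± 0.507 in the knockdown (SD, n = 3). WWC3 rose by 3.3, the ephrin receptor EPHA6 by 2.85, SLC16A7, a monocarboxylate transporter, by 2.83, the endothelin receptor EDNRB by 2.82, the interferon-induced IFI44L by 2.56, ANKRD1 by 2.32 and the prostaglandin receptor PTGFR by 2.25. All of these were under 10 CPM in the knockdown. The lowest change was in RFPL4A, which has near-identical copies, at 3.23 ± 0.129 CPM in the control and 0.32 ± 0.268 in the knockdown (log2 fold change -3.32). LINC01963 fell by 2.31, DOK3 by 1.76, IQCN by 1.66, LINC01424 by 1.64, PRR22 by 1.64, MT-RNR1 by 1.62 and VGF, a neuropeptide precursor, by 1.58.

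Genes of extracellular matrix and adhesion were higher after NEAT1 knockdown, 36 of 45 with none lower (37 over the list alone, median 0.59, camera adjusted p = 3.56e-17, adjusted p = 0.176 with an estimated correlation). The collagens COL5A2 and COL6A2 rose by 1.09 and 1.04, fibronectin FN1 from 94.9 ± 4.76 to 183 ± 18.8 CPM (SD, n = 3, log2 fold change 0.94) and the fibronectin receptor subunit ITGA5 by 0.85. TGF-beta targets were higher, 18 of 27 with 3 lower (19 and 4 over the list alone, median 0.33, camera adjusted p = 0.000597, adjusted p = 0.176 with an estimated correlation), among them ID1 (0.91), CCN1 (0.78), LTBP2 (0.72) and KLF10 (0.60). Fibroblast markers, listed as a sign of other cells, were higher in 8 of 10 with none lower (median 0.77, camera adjusted p = 9.91e-05, adjusted p = 0.176 with an estimated correlation). POSTN rose by 2.25, LUM by 1.75 and COL3A1 by 1.43, to 4.90 ± 0.313, 2.79 ± 0.326 and 11.9 ± 0.86 CPM. Keratinocyte markers were higher in 5 of 9 with none lower (median 0.35, camera adjusted p = 0.000736, adjusted p = 0.176 with an estimated correlation), led by KRT17 (1.87) and LAMB3 (1.27).

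All 15 mitochondrially encoded genes tested fell after NEAT1 knockdown (median -1.14, camera adjusted p = 1.21e-11, adjusted p = 0.324 with an estimated correlation). MT-RNR1 fell from 7248 ± 356 to 2354 ± 194 CPM (SD, n = 3), and MT-CO3, MT-ND1 and MT-ND3 fell by 1.46, 1.45 and 1.29 on the log2 scale. Nuclear genes of respiratory complex I were lower as well, 20 of 38 with none higher (22 lower and 1 higher over the list alone, median -0.26, camera adjusted p = 8.63e-06, adjusted p = 0.562 with an estimated correlation), with NDUFB3 and NDUFB6 at -0.62 and NDUFB1 at -0.56. Cholesterol synthesis genes were lower in 13 of 24 with 1 higher (median -0.31, camera adjusted p = 8.63e-06, adjusted p = 0.176 with an estimated correlation). IDI1, which makes dimethylallyl diphosphate, fell from 167 ± 2.2 to 61.3 ± 2.79 CPM (SD, n = 3, log2 fold change -1.45), ACAT2 by 1.26 and INSIG1, a sterol sensor of the endoplasmic reticulum, by 1.04. SC5D, a late enzyme of the pathway, was the exception and rose by 0.93. For mitochondrially encoded genes, the ARID set control also lay below the NEAT1 set control, by about as much (median -1.15).

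**Figure D5:**
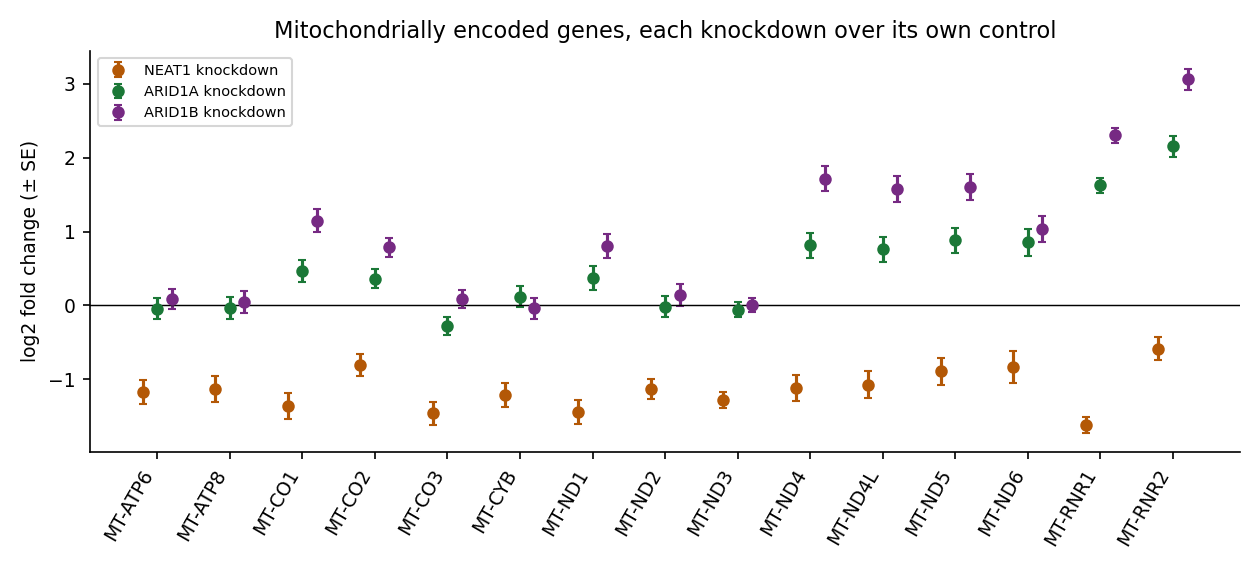
Log2 fold change (y axis, with SE) of each mitochondrially encoded gene (x axis) in the NEAT1, ARID1A and ARID1B knockdowns, each over its own control. After NEAT1 knockdown all 15 lie below 0, while MT-RNR2 lies at 2.15 and 3.06 after ARID1A and ARID1B knockdown.

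Among RNA-processing genes, 15 of 37 for paraspeckle proteins were lower and 4 higher after NEAT1 knockdown (16 lower over the list alone, median -0.12, camera adjusted p = 0.00955, adjusted p = 0.391 with an estimated correlation). The cold-inducible RBM3 fell by 0.58 and SFPQ by 0.53. Of 26 hnRNP genes 13 were lower and none higher (15 over the list alone, median -0.20, camera adjusted p = 8.68e-05, adjusted p = 0.176 with an estimated correlation), led by HNRNPM (-0.73) and HNRNPAB (-0.42), and PTBP2 was also lower (-0.41). Of 40 core spliceosome genes 15 were lower and 1 higher (17 lower over the list alone, median -0.17, camera adjusted p = 0.000116, adjusted p = 0.41 with an estimated correlation), among them SF3B4 (-0.55), SF3B6 (-0.50) and U2AF2 (-0.45). SWI/SNF subunits were 7 lower and 3 higher of 29 (camera adjusted p = 0.557), with ACTL6A at -0.55 and BCL11B at -0.73. Of 17 genes around NEAT1 on 11q13, 3 were higher and 3 lower (camera adjusted p = 0.624). Heat shock genes had 7 higher and 3 lower of 21 (camera adjusted p = 0.429), with HSPA1A at 54.6 ± 1.84 CPM in the control and 197 ± 27.3 in the knockdown (SD, n = 3, log2 fold change 1.84, adjusted p = 4.38e-09). Immediate early genes were 13 higher and 3 lower of 30 (median 0.18, camera adjusted p = 0.00633, adjusted p = 0.324 with an estimated correlation), with KLF6 at 1.13 and JUN at 0.98 but FOS at -1.08. Histones were 11 higher and 1 lower of 23 (median 0.29, camera adjusted p = 0.00522, adjusted p = 0.391 with an estimated correlation), with H2BC11 at 1.13.

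NEAT1 knockdown gave 6756 calls among 16221 genes, 3514 higher and 3242 lower, with 321 at least 2-fold higher and 332 at least 2-fold lower and a median size of 0.45. NEAT1 stood at 48.8% of its control, and the libraries were shallower than those of the ARID set. In these counts of poly(A)-selected RNA it was thus reduced and not lost, and its 188 CPM lay above the 108 CPM of the ARID set control. Counts per gene do not tell transcripts of NEAT1 apart, and transcripts without a poly(A) tail may be missed. How far paraspeckles themselves were reduced was not measured.

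The NEAT1 and ARID knockdowns have separate controls. Their calls were compared to ask whether reducing the paraspeckle RNA and reducing SWI/SNF subunits touch the same genes. NEAT1 and ARID1A shared 1512 genes called higher, against 1005 for independent lists, and 1460 called lower, against 907.3 (Fisher's exact test, one-sided, p = 1.12e-96 and 2.42e-121), while 697 were higher after NEAT1 and lower after ARID1A knockdown and 486 the reverse. NEAT1 and ARID1B shared 1629 higher, against 1171, and 1620 lower, against 1048 (Fisher's exact test, one-sided, p = 1.27e-74 and 7.91e-122), with 817 higher after NEAT1 and lower after ARID1B knockdown and 603 the reverse. Genes are not independent, so these p-values describe the overlap over genes only. Across 16123 genes fold changes correlated at r = 0.234 and 0.246, and unchanged simulated groups gave -0.00328 and 0.00203. In all 3 knockdowns 1177 genes were higher and 1224 lower. RHOB, a small GTPase, rose by 0.99, 1.12 and 1.64 after ARID1A, ARID1B and NEAT1 knockdown, TXNIP, an inhibitor of thioredoxin, by 2.22, 2.16 and 1.80, the neurofilament NEFL by 1.05, 1.05 and 1.82, KRT17 by 1.48, 1.82 and 1.87 and SLC2A3 by 2.43, 2.51 and 1.38, and ACAT2 fell by 0.46, 0.84 and 1.26. Against the NEAT1 set control, RHOB (0.64 and 0.76), TXNIP (0.76 and 0.69), NEFL (0.20 and 0.20) and SLC2A3 were called higher in both ARID knockdowns, while KRT17 (-0.02) and ACAT2 (0.13) were not called after ARID1A knockdown. The NEAT1 comparison uses that control too, so agreement with NEAT1 knockdown there may come in part from shared libraries.

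The effects were also tested against each other in all 15 libraries. The NEAT1 effect differed from the ARID1A effect in 7191 of 18145 genes, 3776 higher and 3415 lower, and from the ARID1B effect in 8529, 4442 higher and 4087 lower. Upper-quartile scaling left 30.6% and 31.2% of these calls higher, against 52.5% and 52.1% with TMM, and moved the median of all genes to -0.18 and -0.21. HSPA1A rose after NEAT1 knockdown and fell after ARID1A knockdown (difference 3.18, SE 0.12, adjusted p = 1.32e-13), and MT-RNR1 fell and rose (difference -3.23, SE 0.15, adjusted p = 2.22e-12). INSIG1 fell after NEAT1 knockdown and rose after ARID1B knockdown (difference -1.82, SE 0.101, adjusted p = 4.32e-11), and SC5D did the reverse (difference 1.37, SE 0.0713, adjusted p = 1.69e-11). These differences take the ARID effects over the ARID set control. With the NEAT1 set control HSPA1A was still lower after ARID1A knockdown (-0.68) and INSIG1 higher after ARID1B knockdown (0.64), but MT-RNR1 was lower after ARID1A knockdown (-2.18) and SC5D was at 0.05 after ARID1B knockdown (adjusted p = 0.46).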

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

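The tests of the share of mitochondrial counts, of separate culture or preparation of the ARID set control, of carry-over of RNA without a poly(A) tail, of nuclear respiratory genes and of where the 7-mers lie and how many lower genes hold them were chosen after the result was seen.

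Knockdown effects were compared by testing their difference itself, and these are the differences past the threshold that are reported. The NEAT1 effect differed from the ARID1A effect in 7191 genes and from the ARID1B effect in 8529. Of 41 arrangements of the libraries, the real one included, 1 gave as many for either difference, and the highest others gave 3636 and 5693. The arrangements mix knockdown and control libraries within each set. They test whether knockdown and control libraries are exchangeable in both sets, which can be excluded at 0.05 for these libraries. Groups that differ for a reason other than the knockdown, such as separate preparation, would give the same outcome. The arrangements do not test whether the effects are equal. Among genes called in both comparisons, 1119 went in opposite directions in NEAT1 and ARID1A and 1326 in NEAT1 and ARID1B, with the difference itself called. The ARID knockdowns differed from each other in 7109 genes. HSPA1A differed between the NEAT1 and ARID1A effects by 3.18 on the log2 scale (SE 0.12), HSPA1B by 1.84 (SE 0.122), MT-RNR1 by -3.23 (SE 0.15) and GADD45B, a stress-induced gene, by -2.29 (SE 0.144). Between the NEAT1 and ARID1B effects INSIG1 differed by -1.82 (SE 0.101) and SC5D by 1.37 (SE 0.0713). The median difference of mitochondrially encoded genes was -1.66 against ARID1A and -1.84 against ARID1B. These differences rest on the ARID set control, which differed from the NEAT1 set control by -1.15 in the median of that list. Over the NEAT1 set control, ARID1A knockdown gave -2.18 for MT-RNR1, below the -1.62 of NEAT1 knockdown, -0.25 for GADD45B and 0.41 for HSPA1B, which was also higher after NEAT1 knockdown, and ARID1B knockdown 0.05 for SC5D (adjusted p = 0.46).

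For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. In each of these only 1 of 10 splits, the real one, reached the real count, and the highest other split called 0 genes, against 9481 for ARID1A, 11012 for ARID1B, 6756 for NEAT1, 7109 between the ARID knockdowns and 11725 between the controls. Groups of 3 were not tested for single outlying libraries.

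The ARID set control stood apart from both ARID knockdowns and from the NEAT1 set control, and the median difference of hypoxia targets between the controls was -0.92. The tables argue against depth (-0.93 after thinning to 1 depth) and against GC content and transcript length (-0.98 after bin medians were removed) as its source. They also argue against the share of mitochondrial transcripts, which would move all other genes by 0.0857 on the log2 scale, in the other direction. Carry-over of RNA without a poly(A) tail was not tested as a source here. Replication-dependent histones, which lack such a tail, were also lower in the ARID set control. The ARID set control may have been cultured or prepared apart from the 6 knockdown libraries. Fold changes of either ARID knockdown and of the NEAT1 set control, all against that control, covaried by at least 0.264 more than a shared control gives in simulated data. The labels give no batch and the control is a single group. For the ARID knockdowns, separate preparation therefore cannot be told apart from an effect that both share. Such an effect cannot account for the difference between the controls, neither of which received an ARID siRNA.

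Mitochondrially encoded transcripts were lower after NEAT1 knockdown. The tables argue against depth, since the NEAT1 set libraries differed little in it, from 12821939 to 15685283 counts. Thinning therefore changed little and tested little (median -1.14 after it and -1.14 before it). The tables also argue against less carry-over of RNA without a poly(A) tail, since replication-dependent histones, which lack one, had a median of 0.29. Nuclear genes of complexes II to IV, whose values had not been seen when the test was written, were lower in 11 of 23 with none higher (median -0.22, at percentile 0.01 among 10000 random lists matched on level, the smallest they can give), which is consistent with a lower amount of respiratory-chain transcripts of both genomes. The random lists were drawn gene by gene, so this percentile allows neither for correlation among respiratory genes nor for the spread between libraries. The ARID set control, which received no NEAT1 siRNA, also lay below the NEAT1 set control in the mitochondrially encoded genes (median log2 fold change -1.15). Their share of counts was 8.56% in the NEAT1 set control, 4.24% after NEAT1 knockdown and 2.97% in the ARID set control. A fall caused by the knockdown therefore cannot be told apart from a NEAT1 set control that stands high. Whether culture differed between the groups is not recorded and stays open.

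Genes lower after ARID1A knockdown than after ARID1B knockdown and in the control may be direct off-targets of the ARID1A siRNA. The 7-mer GCCTCTA, chosen in 1 part of the genes, had a z of -6.55 in the other part, beyond the bound of -4 set before the result was seen, and it occurs in the ARID1A transcript once, in exon 11 (chromosome 1, 26767959 to 26767965), as does GACCGTT. Of the 16229 7-mers tested 33.3% occur in that transcript, so this match alone decides little. Of 158 genes lower by at least 0.5 in both comparisons 75 held either 7-mer, which leaves 83 with neither, and the siRNA sequences are not given in the labels. No biological explanation of the group was tested.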

How the results depend on the processing

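The NEAT1 set control as the control, thinning to 1 depth and leaving out mitochondrially encoded genes were chosen after the data were seen. With the NEAT1 set control, ARID1B gave 6569 calls against 11012 and the ARID knockdowns shared 4332 against 7200, and the cause was not tested. Of 257 named ARID values, 110 kept direction and call there, 50 kept direction only, 44 were called in the opposite direction and 53 were opposite without a call. Camera with an estimated correlation called 0 lists (16 at an unadjusted p under 0.05) against 59, with fry at 81 and a replicate block at 57. The other totals of called and shared genes stayed within 1.5 times, though with upper-quartile factors the calls higher fell to 30.4% between the controls. Planned settings gave 8323 to 9570 calls for ARID1A, 9876 to 11149 for ARID1B, 5311 to 7855 for NEAT1, 6121 to 7095 between the ARID knockdowns, 6415 to 7775 and 7802 to 8942 for the NEAT1 effect less the ARID1A and ARID1B effects, and 9551 to 12002 between the controls. Without 1 library each, in the same order, the calls were 8292 to 9134, 10061 to 10546, 5080 to 7943, 5675 to 6990, 6355 to 7947, 7769 to 8996 and 10678 to 11118. Shared calls were then 6284 to 6960 for the ARID knockdowns, 2225 to 3215 for NEAT1 and ARID1A and 2404 to 3471 for NEAT1 and ARID1B. Of 500 named values, 496 to 500 kept direction and call under planned settings, and of 3000 values without 1 library each, 2985 did and 15 kept direction only. With a replicate block, ARID1A, ARID1B and NEAT1 gave 9195, 10748 and 5395 calls, but only 6 of 24 libraries correlated best with the library of their own number, so the numbers are not taken as pairs. Thinned to 1 depth, they gave 8059, 9521 and 6620 calls, so lower depth cost calls in each.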

Other observations

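The test of Alu elements for a shift shared by all knockdowns and the comparisons with the NEAT1 set control were chosen after the result was seen.

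Several fixed lists beyond those described moved in the ARID knockdowns against the ARID set control. Genes of mitosis and G2/M were lower in 19 of 34 with 5 higher after ARID1A knockdown (median -0.17, camera adjusted p = 0.00649, adjusted p = 0.325 with an estimated correlation) and in 19 with 7 higher after ARID1B knockdown (20 lower adjusted over the list alone, median -0.22, camera adjusted p = 0.0117, adjusted p = 0.396 with an estimated correlation). This list was higher in the ARID set control than in the NEAT1 set control (25 higher, 6 lower, median 0.31), and against the NEAT1 set control it was higher in 14 with 2 lower after ARID1A knockdown (median 0.14) and in 12 with 1 lower after ARID1B knockdown (median 0.09). Genes of extracellular matrix and adhesion were higher in 25 of 45 with 7 lower after ARID1A knockdown (median 0.20, camera adjusted p = 0.00267, adjusted p = 0.282 with an estimated correlation) and in 30 with 6 lower after ARID1B knockdown (7 lower adjusted over the list alone, median 0.27, camera adjusted p = 0.000345, adjusted p = 0.274 with an estimated correlation), and against the NEAT1 set control it was higher in 13 with 20 lower (median -0.14) and higher in 10 with 8 lower (median -0.06). ITGA5 was called higher against either control (0.34 and 0.38 against the NEAT1 set control). TGF-beta targets were higher in 15 of 28 with 1 lower after ARID1A knockdown (16 higher adjusted over the list alone, median 0.26, camera adjusted p = 0.00258, adjusted p = 0.207 with an estimated correlation), with LTBP2 at 1.19 and CCN1 at 0.93, and against the NEAT1 set control the median was 0.08, with CCN1 called higher (0.63) and LTBP2 not called (0.07). Nuclear-retained long noncoding RNAs were higher in 15 of 27 with 4 lower after ARID1A knockdown (median 0.47, camera adjusted p = 0.000676, adjusted p = 0.219 with an estimated correlation), and lower in 17 with 1 higher (median -0.28) against the NEAT1 set control.

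After NEAT1 knockdown, chaperones of the endoplasmic reticulum were higher in 12 of 24 with 3 lower (median 0.19, camera adjusted p = 0.0487, adjusted p = 0.529 with an estimated correlation), DNA replication genes lower in 16 of 40 with 5 higher (median -0.13, camera adjusted p = 0.0487, adjusted p = 0.713 with an estimated correlation) and hypoxia targets higher in 14 of 37 with 1 lower (median 0.10, camera adjusted p = 0.0492, adjusted p = 0.713 with an estimated correlation). Neuronal genes went both ways, 11 higher and 10 lower of 27 (12 and 11 adjusted over the list alone, camera adjusted p = 0.913), with NEFL at 1.82 and the secretory granule protein CHGA at -1.55. Fibroblast markers were higher in 6 of 9 with none lower after ARID1B knockdown (median 0.38, camera adjusted p = 0.0348, adjusted p = 0.25 with an estimated correlation), and in 1 of 12 with 3 lower against the NEAT1 set control. Of blood cell markers 4, 4 and 2 were tested for ARID1A, ARID1B and NEAT1, with 2, 1 and 1 higher and 0, 1 and 0 lower (for ARID1B 0 lower adjusted over the list alone). Of hepatocyte markers 2, 2 and 1 were tested, with 2, 1 and 0 higher and none lower.

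Genes with an Alu element in the 3' UTR may be lower after NEAT1 knockdown because inverted pairs hold transcripts in paraspeckles. Genes with Alu elements in both orientations had a mean residual log2 fold change of -0.0888 (688 genes), and those with 1 orientation -0.0185 (2134 genes). The difference was -0.0703 (permutation p = 3e-05), in the direction predicted in advance for inverted pairs. Values were permuted over genes, so these p-values allow neither for correlation among genes nor for the spread between libraries. Gene counts do not show where in the cell transcripts lie, so retention in paraspeckles itself was not tested. A shift shared by the knockdowns is also consistent with the values, since genes with any Alu element were lower by -0.0239 after ARID1A knockdown (permutation p = 0.00691) and by -0.0412 after ARID1B knockdown, where the step between both and 1 orientation was -0.0416 (permutation p = 0.0358). For the difference between the NEAT1 and ARID1A effects the step was -0.0570 (permutation p = 0.00251), and for that between the NEAT1 and ARID1B effects -0.0317 (permutation p = 0.112). Against genes with 1 orientation matched on UTR length and GC content, genes with both were lower by as much after ARID1B (-0.0987, SE 0.0181) as after NEAT1 knockdown (-0.0941, SE 0.0148), and less so after ARID1A knockdown (-0.0435, SE 0.0156). The matched difference was 0.0011 (SE 0.0187) between the NEAT1 and ARID1B effects and -0.0560 (SE 0.0177) between the NEAT1 and ARID1A effects, so whether a part belongs to NEAT1 stays open.

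Seed matches of the other siRNAs were tested in the same way as those of the ARID1A siRNA. For genes lower after ARID1B than after ARID1A knockdown the chosen 7-mer was GAGAGAA. Its z in the other part of the genes was 3.83, short of the bound of 4. For genes lower after NEAT1 knockdown CCTGTAA had a z of -1.95, within its spread of 1 of the bound of -2. Neither test decides. CCTGTAA is also part of the Alu sequence whose words were used to call Alu elements. Its z therefore cannot tell a seed match from the shift of genes with Alu elements.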
